A study of Mus musculus with 6 samples.

How the data were processed

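The data are 6 single-sample Affymetrix expression arrays, 3 of lung macrophages from mice that received KRAS_CL cells and 3 from mice that received KRAS IKKa low cells. Per the labels' protocols, total RNA was extracted with Trizol and labelled as biotinylated cRNA from 150 ng. The deposited values are log2 probe set signals made by the authors with Affymetrix Expression Console, per the submitters' processing notes. Its version, the summarisation algorithm and the background correction are not given in the sources used here. The log base was read from the values, so fold sizes rest on that reading. Samples were assigned to groups and replicate numbers from their titles. The labels call the arrays biological replicates but do not say how many mice stand behind each.

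The table held 28846 probe sets. Of these, 19572 were named to 1 gene symbol, 0 to several and 9274 to none. The platform's gene table supplied the names, and all 19572 Entrez identifiers matched a RefSeq gene table for GRCm38.p6, which changed 0 symbols. No genome was used, the labels name no build, and no coordinates are given. For the 55 genes with more than 1 probe set the probe set with the highest mean stood for the gene, which left 19505 genes. Probe sets of 39 genes carried values identical to those of another gene. No filter on dim genes was applied. Control probe sets comparing transcript ends, which had been planned as a quality measure, were not used here.

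Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, 6 arrays, no covariate), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 3 arrays per group an exact permutation test of a single value cannot go below p = 0.1. A total of 37 gene lists, 22 of pathways, 13 of cell types and 2 of sample quality, were fixed before the data were examined, as were the tests and the rule for naming genes. They held 790 entries, of which 724 were measured. The 35 pathway and cell type lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Genes such as Cd68 and Stat1 had no probe set named to them and were not analysed here.

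The named genes were the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, and up to 4 members with the smallest unadjusted p per list. Predicted genes were counted only, and 73 were called. Genes outside this rule are said to have been chosen after their values were seen.

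A background line was set after seeing the data at 6.51, the 95th percentile of the means of the 23 background probe sets. The 5222 probe sets labelled as negative controls, whose means had a 95th percentile of 10.03, were not used for it. Where a gene lay below it on all 3 arrays of a group, the fold is given as "at least", the brighter group's mean against the line or the dim array's own value, whichever was higher. In all, 9772 genes lay below the line on all 6 arrays, and 300 of them were called. No fold is given for those.

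The gene and list tests were tested on simulated data with 19505 genes and the real spread, 50 genes changed at each of 4 sizes. For this comparison the gene test recovered 4%, 78%, 100% and 100% of changes of 0.5, 1, 2 and 3 on the log2 scale, and called 12 unchanged genes. A list shifted by 0.5 was called by camera (adjusted p = 5.23e-21), and 0 other lists were. The simulated noise was independent between genes and had the same spread in both groups. It therefore could not check the list test on correlated genes or the effect of an outlying array. The alternatives were quantile normalization, median centring, averaging of probe sets, leaving out the dimmest 30% or 50% of genes, trend and robust variance estimation, array weights, a replicate block, leaving out each array, testing every probe set, other thresholds, an unmoderated model and other list tests. Leaving out KRAS_CL replicates 1 and 2 together was added after seeing the data, and leaves 1 KRAS_CL array, so that the spread comes from the KRAS IKKa low arrays alone. Alternatives for linear values did not apply.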

Results

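Gene expression was measured on 6 Affymetrix arrays of macrophages taken from mouse lungs bearing adenocarcinoma. Wild-type C57BL/6 mice received either KRAS_CL cells or KRAS IKKa low cells through the trachea, and lung macrophages were isolated 1.5 months later. IKKa is the kinase encoded by Chuk, and the labels call its level low in the injected cells, not in the mice or their macrophages. The labels do not spell out CL. Each group had 3 arrays, described as biological replicates. The values are probe set signals on a log2 scale, a base read from the values themselves, and 19505 genes were tested. The number of arrays limits the precision. Array medians over the genes lay between 5.98 and 6.05. The first principal component held 72.4% of the variance and separated the groups. The second held 13.6% and set KRAS_CL replicate 3 apart from the other arrays. Across genes, Pearson correlations were 0.985 to 0.995 within KRAS_CL, 0.994 to 0.995 within KRAS IKKa low and 0.960 to 0.970 between the groups. Genes are not independent replicates in these correlations.

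The single comparison asked how macrophages from lungs that received KRAS IKKa low cells differed from those of lungs that received KRAS_CL cells. Y-linked genes separated the groups completely, with Eif2s3y at 3.23 on KRAS_CL and 10.37 on KRAS IKKa low arrays. The labels give no sex, so a possible sex difference cannot be separated from the injected cells in any result below. On the KRAS IKKa low arrays Hp and Saa3 were higher and Il1b was lower. Of the gene lists, 21 of 24 NRF2 antioxidant targets and 17 of 22 lysosomal genes rose, while all 32 cell cycle genes and 8 of 10 MHC class II genes fell. Camera called these lists with a preset correlation, and their adjusted p was 0.0801, 0.226, 0.226 and 0.234 with an estimated correlation. Hp, which encodes the haemoglobin-binding protein haptoglobin, rose from 5.75 ± 0.18 to 16.19 ± 0.38 (log2, SD, n = 3 per group), at least 822-fold. Ccl17, a chemokine that attracts T helper cells, fell from 15.46 ± 2.38 to 6.62 ± 0.48 (SD, n = 3), and its KRAS_CL arrays read 13.49, 14.78 and 18.10. Chuk was not analysed here.

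In limma's moderated test, 3207 of the 19505 genes passed an adjusted p of 0.05, 1616 of them higher and 1591 lower on the KRAS IKKa low arrays. Of these, 1702 changed by at least 1 on the log2 scale, 760 upward and 942 downward. The arrays of the groups did not overlap for 31.8% of all genes, against 10% expected by chance for 3 against 3. Without the moderation of variances, 1313 genes passed. Without KRAS IKKa low replicate 1, 1067 genes were higher.

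Genes of the Y chromosome separated the groups completely. Eif2s3y, a translation initiation factor, measured 3.23 ± 0.13 on KRAS_CL arrays and 10.37 ± 0.07 on KRAS IKKa low arrays (SD, n = 3), at least 14.6-fold higher (limma adjusted p = 1.39e-08). Uty and Kdm5d, a pair of Y-linked demethylase-family genes, rose at least 14.03-fold and at least 2.51-fold. All 3 measured members of the sex-linked list rose, also adjusted over the list alone. Xist and Ddx3y, also on that list, had no probe set named to them and were not analysed here. X-linked genes with a Y-linked partner, chosen after the values were seen, moved the other way. Eif2s3x fell by 1.18, Kdm6a fell by 1.01 and Kdm5c fell by 0.78 on the log2 scale (limma adjusted p = 0.000685, 0.00183 and 0.0259), and Ddx3x did not pass, with a log2 fold change of -0.47 (adjusted p = 0.0815). Ddx3x passed without KRAS_CL replicate 3, with array weights and with trend and robust estimation (adjusted p = 0.0403, 0.0422 and 0.0477). Kdm5c no longer passed without KRAS_CL replicate 2 or KRAS IKKa low replicate 1 or 2 (adjusted p = 0.0881, 0.0511 and 0.0948). The labels give no sex, and this difference ran along with every gene group described here.

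**Figure D1:**
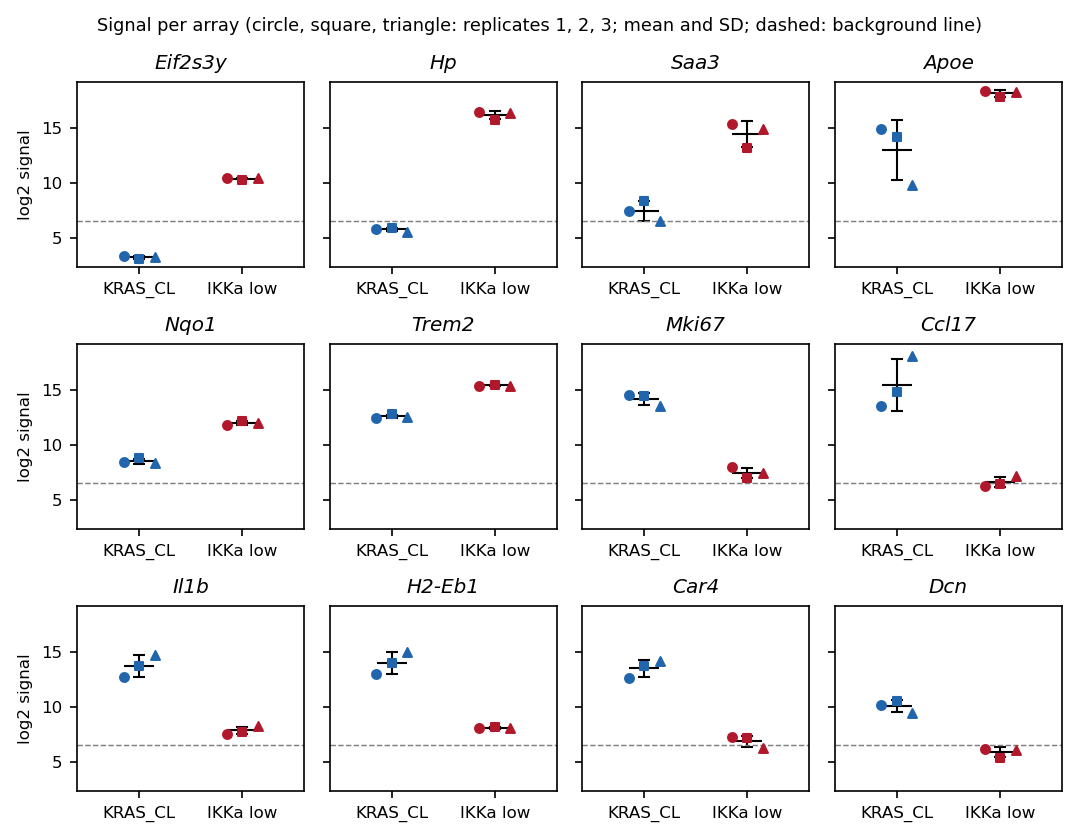
Log2 signal of 12 genes on each array, KRAS_CL in blue and KRAS IKKa low in red, with circles, squares and triangles for replicates 1, 2 and 3, horizontal bars for the mean and whiskers for the SD. The dashed line is the background line at 6.51, below which Eif2s3y and Hp lay on all 3 KRAS_CL arrays.

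Among the other large rises, Il1f9, an interleukin 1 family cytokine, rose by 7.21 ± 0.29 (log2 fold change ± SE) and Saa3, an acute phase protein of macrophages, by 7.01 ± 0.57. Layn rose by 5.44 ± 0.21 and Pla2g2d, a secreted phospholipase, by 5.29 ± 0.32. Ednrb, an endothelin receptor, rose from 6.22 ± 0.63, a mean below the background line, to 11.55 ± 1.82 (SD, n = 3). Prg4 was at least 9.41-fold higher. The KRAS IKKa low arrays read 12.67, 9.45 and 12.53 for Ednrb and 11.65, 8.14 and 9.43 for Prg4. Apoe, the lipid carrier apolipoprotein E, rose by 5.18 ± 1.04 (limma adjusted p = 0.00776), but its KRAS_CL arrays read 14.89, 14.15 and 9.83, and the call ended when the variance model used a trend and robust estimation (adjusted p = 0.116).

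Among the other large falls, Grem1, a secreted BMP antagonist, fell from 13.70 ± 1.80 to below background, at least 147-fold. Tnc, the matrix protein tenascin C, fell from 13.95 ± 1.79 to 6.46 ± 0.43 (SD, n = 3), a mean below the background line. KRAS_CL replicate 3 read 11.63 for Grem1 and 11.89 for Tnc, against 14.65 to 15.07 on replicates 1 and 2. The fibroblast markers Bgn and Igfbp7, described below, were also lower on replicate 3 than on replicates 1 and 2. Whether the Grem1 and Tnc signal came from macrophages or from fibroblasts in the KRAS_CL samples was not tested. Rnase2a fell by 7.45 ± 0.91 (log2 ± SE), with KRAS_CL arrays at 14.16, 15.14 and 18.49, and Ch25h, which makes 25-hydroxycholesterol, fell by 7.25 ± 0.32. The histone gene H2ac15 fell by 5.84 ± 0.46. Its value is uncertain, as is that of Rnase2a and of Gsta2 below, because close relatives in their gene families can share probes.

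Cell division genes were lower as a group. All 32 measured members of the cell cycle list fell, also adjusted over the list alone, with a median log2 fold change of -3.62. Mki67, a marker of cycling cells, went from 14.19 ± 0.54 to 7.45 ± 0.49 (SD, n = 3). Rrm2, a subunit of ribonucleotide reductase, fell by 6.00 ± 0.35 (log2 ± SE), and Plk1, a mitotic kinase, fell by 5.57 ± 0.22. Ube2c, which drives mitotic exit, was at least 35.4-fold lower, and Bub1 and Cdk1 at least 6.14-fold and 4.09-fold lower. The list was called by camera with a preset correlation of 0.01 (adjusted p = 1.80e-40), and its adjusted p was 0.226 with an estimated correlation.

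Fibroblast and smooth muscle markers moved in the same direction on some arrays. Of 28 measured, 5 fell and none rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00857, and adjusted p = 0.557 with an estimated correlation). Dcn, the matrix proteoglycan decorin, was at least 11.8-fold lower, and Bgn and Igfbp7 fell by 3.49 ± 0.70 and 3.45 ± 0.67 (log2 ± SE). Postn and Loxl1, the latter named after its values were seen, also fell. Postn averaged 6.27 on KRAS_CL arrays, already below the background line. Loxl1 did not pass without KRAS_CL replicate 2 (adjusted p = 0.0548) or KRAS IKKa low replicate 1 (0.0535). With trend and robust estimation Bgn, Igfbp7 and Loxl1 had adjusted p of 0.105, 0.0897 and 0.0768. Acta2 and Tagln, contractile genes chosen after the values were seen, did not pass, with adjusted p of 0.0855 and 0.0736. KRAS_CL replicate 3 lay 0.04 and 0.08 above the KRAS IKKa low mean for them, while replicates 1 and 2 lay 4.52 and 4.30 above it, and both genes passed without replicate 3 (adjusted p = 7.69e-06 and 1.35e-06). They passed with array weights too (0.00559 and 0.00386), as did Tagln with a replicate block (0.0490). Bgn and Igfbp7 lay 1.53 and 1.71 above the KRAS IKKa low mean on replicate 3, against 4.46 and 4.33 on replicates 1 and 2. Without replicate 3, 13 of the 28 markers fell, 11 fell with array weights and 2 with trend and robust estimation. On replicate 3 the cell cycle list still lay 2.95 above the KRAS IKKa low mean. With the dimmest 50% of genes left out the adjusted p of the fibroblast list was 0.122.

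**Figure D2:**
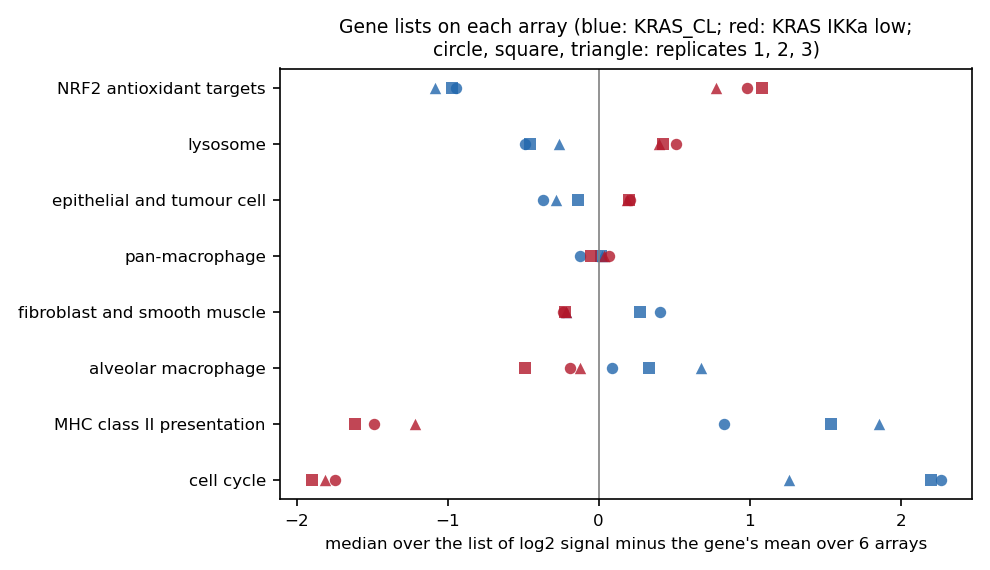
Median over the members of 8 gene lists, per array, of the log2 signal minus each gene's mean over the 6 arrays, with KRAS_CL in blue, KRAS IKKa low in red, and circles, squares and triangles for replicates 1, 2 and 3. On the fibroblast and smooth muscle list KRAS_CL replicate 3, at -0.22, lay with the KRAS IKKa low arrays, while on the cell cycle list it lay at 1.26 above all 3 of them.

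NRF2 antioxidant targets were higher as a group. Of 24 measured, 21 rose and none fell (22 and 0 adjusted over the list alone), and the median log2 fold change was 1.89. Gsta3, a glutathione S-transferase, rose by 5.23 ± 0.16 (log2 ± SE). Srxn1, which repairs oxidised peroxiredoxins, rose by 3.59 ± 0.20, the quinone reductase gene Nqo1 by 3.51 ± 0.18 and Pgd, of the pentose phosphate pathway, by 2.66 ± 0.15. Gsta2, from the same enzyme family as Gsta3 but outside the list, rose at least 31.9-fold. The list had an adjusted p of 4.26e-23 by camera, and adjusted p = 0.0801 with an estimated correlation.

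Epithelial and tumour cell markers rose on the same arrays. Of 28 measured, 11 rose and 2 fell (13 and 2 adjusted over the list alone), and 16 lay below background in both groups (camera adjusted p = 0.000309, and adjusted p = 0.226 with an estimated correlation). Scgb1a1, of airway club cells, was at least 3.86-fold higher and Muc1 at least 3.17-fold higher. The keratin gene Krt7 rose by 2.36 on the log2 scale, and the claudin gene Cldn18 rose from 6.05 ± 0.41 to 8.31 ± 0.49 (SD, n = 3). Krt8 and Krt18, named after their values were seen, went from 6.17 ± 1.11 to 9.002 ± 0.19 and from 7.33 ± 1.23 to 10.30 ± 0.23. The KRAS_CL means of Cldn18 and Krt8 lay below the background line. The members that fell, also named afterwards, were Cdh1, which fell by 2.89, and Spint1, which fell by 1.82. Cdh1 did not pass with trend and robust estimation (adjusted p = 0.0751).

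Lysosomal genes rose in 17 of 22 cases and none fell, with the same counts adjusted over the list alone (camera adjusted p = 8.28e-11, and adjusted p = 0.226 with an estimated correlation). The protease gene Ctsl rose by 2.49 ± 0.18 (log2 ± SE), the acid glucosidase gene Gaa by 1.78 ± 0.17 and Atp6v1h, of the proton pump, by 1.55 ± 0.18. Of 21 lipid handling genes, 10 rose and 3 fell (11 and 3 adjusted over the list alone). Trem2, a lipid-sensing receptor, rose by 2.82 ± 0.15, the lipid droplet gene Plin2 by 1.64 ± 0.16 and Gpnmb by 1.14 ± 0.15, whereas Pparg, a nuclear receptor for fatty acids, fell by 2.46 ± 0.25. Abcg1 and Nr1h3, named after their values were seen, were the other members that fell, and neither passed without KRAS IKKa low replicate 2 (adjusted p = 0.0569 and 0.0685) or replicate 3 (0.0632 and 0.0817). The lipid list had a camera adjusted p of 0.00135, and adjusted p = 0.538 with an estimated correlation.

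Cholesterol synthesis genes fell in 13 of 19 cases and none rose (15 and 0 adjusted over the list alone; camera adjusted p = 8.16e-09, and adjusted p = 0.135 with an estimated correlation). Idi1 fell by 2.58 ± 0.21, Hsd17b7 fell by 1.99 ± 0.19 and Cyp51 fell by 1.65 ± 0.18 (log2 ± SE). Of 26 glycolysis and hypoxia genes, 10 rose and 1 fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.00264, and adjusted p = 0.300 with an estimated correlation). Hilpda, a hypoxia-induced lipid droplet gene, rose by 2.83 ± 0.18, the phosphofructokinase gene Pfkl by 2.68 ± 0.27 and the glucose transporter gene Slc2a1 by 1.38 ± 0.15. Without KRAS IKKa low replicate 1, 6 of these genes rose, and without KRAS_CL replicate 1 or 3, 2 fell. Without KRAS_CL replicate 3, 1 cholesterol synthesis gene and 3 oxidative phosphorylation genes rose. Adm, the 1 glycolysis and hypoxia gene that fell in the main test, was named after its values were seen. It was at least 15.2-fold lower, and did not pass with trend and robust estimation (adjusted p = 0.0851). Oxidative phosphorylation genes fell in 4 of 28 cases (Cox5a, Cycs, Atp5a1 and Atp5o) and 1 rose, Sdha, named after its values were seen, with the same counts adjusted over the list alone (camera adjusted p = 0.0191, and adjusted p = 0.609 with an estimated correlation). That call ended without KRAS_CL replicate 3 (adjusted p = 0.277) and with array weights (0.0548) or the dimmest 50% of genes left out (0.0695). Sdha and Atp5o did not pass without KRAS_CL replicate 1 (adjusted p = 0.0839 and 0.0544) or replicate 2 (0.0927 and 0.0705). They did not pass without KRAS IKKa low replicate 3 either (0.108 and 0.0519), nor did Sdha without KRAS IKKa low replicate 1 (0.0887) or Atp5o without KRAS IKKa low replicate 2 (0.0737).

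MHC class II genes fell in 8 of 10 cases, also adjusted over the list alone, with a median log2 fold change of -3.05 (camera adjusted p = 7.99e-09, and adjusted p = 0.234 with an estimated correlation). H2-Eb1 went from 13.98 ± 1.004 to 8.08 ± 0.06 and H2-Aa from 16.43 ± 0.74 to 11.59 ± 0.24 (SD, n = 3). Ciita, the transcriptional activator of these genes, was at least 2.78-fold lower. MHC class I presentation genes fell in 7 of 14 cases and none rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.00159, and adjusted p = 0.278 with an estimated correlation). The immunoproteasome gene Psmb10 fell by 1.89 and the peptide transporter gene Tap1 fell by 1.96 on the log2 scale. Without KRAS_CL replicate 2 or KRAS IKKa low replicate 1 or 3, 4 of the class I genes fell, and without KRAS_CL replicate 3, 1 rose.

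In the alternative activation list 13 of 23 fell and 1 rose (14 and 2 adjusted over the list alone; camera adjusted p = 1.19e-06, and adjusted p = 0.226 with an estimated correlation). Mrc1, the mannose receptor, fell by 1.94 ± 0.14 and Cd200r1 fell by 1.25 ± 0.15 (log2 ± SE). The member that rose was Arg1, the arginine-degrading enzyme, named after its values were seen, from 9.63 ± 0.60 to 14.07 ± 2.17 (SD, n = 3). It did not pass with trend and robust estimation (adjusted p = 0.101). In the same list 2 rose without KRAS_CL replicate 3 or KRAS IKKa low replicate 2. In the classical activation list 9 of 21 fell and none rose (11 and 1 adjusted over the list alone; camera adjusted p = 2.19e-05, and adjusted p = 0.226 with an estimated correlation). Il1b, the cytokine interleukin 1 beta, fell by 5.84 ± 0.42, Il18 fell by 3.56 ± 0.35 and Gbp2 fell by 3.18 ± 0.40. The number of classical activation genes that fell was 4 without KRAS IKKa low replicate 3, and 5 without KRAS_CL replicate 2, without KRAS IKKa low replicate 2 or with trend and robust estimation. Type I interferon response genes fell in 7 of 28 cases and 2 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.0225, and adjusted p = 0.566 with an estimated correlation). Herc6 fell by 1.23 ± 0.17. Without KRAS_CL replicate 2 or KRAS IKKa low replicate 2, 4 interferon response genes fell, and without any 1 of the KRAS_CL arrays or KRAS IKKa low replicate 1, 1 rose. The call on the interferon list ended without KRAS_CL replicate 2 (adjusted p = 0.0910) and without KRAS IKKa low replicate 3 (0.0989).

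Chemokine genes fell in 11 of 24 cases and 3 rose (13 and 5 adjusted over the list alone; camera adjusted p = 0.00334, and adjusted p = 0.287 with an estimated correlation). Ccl2, which attracts monocytes, fell by 5.30 ± 0.31 and Ccl4 fell by 1.58 ± 0.15 (log2 ± SE). Those that rose were Cxcl3, by 2.50 ± 0.20, together with Cxcl2 and Ppbp, all of which attract neutrophils. Cxcl2 was named after its values were seen. Without KRAS IKKa low replicate 2, 5 chemokine genes rose. With the dimmest 50% of genes left out the list had an adjusted p of 0.0508, and the growth factor list described next had 0.0509. Growth and angiogenic factors fell in 9 of 25 cases and 1 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.0110, and adjusted p = 0.226 with an estimated correlation). Igf1 fell by 1.99 ± 0.19, Hgf fell by 2.35 ± 0.25 and Inhba fell by 3.68 ± 0.59 (KRAS_CL arrays at 11.74, 12.12 and 14.50), and the growth factor gene Pdgfa rose by 1.72 ± 0.14. Without KRAS_CL replicate 2 or KRAS IKKa low replicate 2, 5 growth and angiogenic factors fell.

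Of the macrophage and monocyte lists, camera called only the alveolar macrophage list in the main test. Of 18 alveolar macrophage genes 8 fell and 1 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.00152, and adjusted p = 0.495 with an estimated correlation). Car4, a carbonic anhydrase, fell by 6.63 ± 0.37, Siglecf fell by 2.73 ± 0.23 and Plet1 fell by 2.33 ± 0.22 (log2 ± SE). Without KRAS_CL replicate 3, 5 alveolar macrophage genes rose, and without KRAS IKKa low replicate 2, 5 fell. Leaving out any array but KRAS_CL replicate 3 left 0 that rose. Of 15 pan-macrophage genes 5 rose and none fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.325), with Itgam up by 2.28 ± 0.23 and Adgre1, a macrophage surface marker, up by 1.39 ± 0.27. The median of that list was -0.01, while its mean was 0.17. Leaving out KRAS_CL replicate 1 or any KRAS IKKa low array left 3 that rose, and without KRAS_CL replicate 3, 2 fell. Of 14 monocyte genes 5 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.592). Ly6c2 was at least 11.7-fold higher and the chemokine receptor gene Ccr2 at least 7.05-fold lower. The median of the monocyte list, -0.12, and its mean, 0.74, differed in sign. Without KRAS_CL replicate 2 or any KRAS IKKa low array 2 monocyte genes fell, and without KRAS IKKa low replicate 1, 3 rose. Of 19 interstitial macrophage genes 2 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.315). Without KRAS_CL replicate 3, 4 of them fell, and without KRAS IKKa low replicate 2, 6 rose and camera called the list higher (adjusted p = 0.0155).

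Markers of other cell types were mostly dim. Of 19 T and NK cell genes 5 fell and 2 rose (8 and 2 adjusted over the list alone), and 12 lay below background in both groups (camera adjusted p = 0.0474, and adjusted p = 0.476 with an estimated correlation). Icos fell from 9.24 ± 0.99 to 6.28 ± 0.73 (SD, n = 3), a mean below the background line, and Il7r rose by 1.79 ± 0.30 (log2 ± SE). That call ended without KRAS_CL replicate 1 or 2 or KRAS IKKa low replicate 1 or 2 (adjusted p = 0.0962, 0.0631, 0.105 and 0.0607) and with the dimmest 30% of genes left out (0.325). Without KRAS_CL replicate 3, 8 of these genes fell, and leaving out any 1 of the 4 arrays just named left 2 that fell. The number that rose was 1 without KRAS_CL replicate 2 or 3 or KRAS IKKa low replicate 2 or 3. Of 17 neutrophil genes 3 rose, also adjusted over the list alone, and 12 lay below background (camera adjusted p = 0.222). Without KRAS IKKa low replicate 1 or 3, 0 neutrophil genes rose, and without KRAS_CL replicate 2, 1 rose. Counts of members that rose and fell were 0 and 1 of 17 for dendritic cells (camera adjusted p = 0.561), 2 and 1 of 16 for B and plasma cells (0.0604), 1 and 0 of 21 for endothelium (0.891) and 1 and 0 of 7 for the erythroid and platelet list (0.409), all the same adjusted over the list alone. The B and plasma cell list was called higher with a replicate block (adjusted p = 0.0344) and without KRAS IKKa low replicate 2 (0.0186), while 1 member rose without KRAS_CL replicate 1 or 2 or KRAS IKKa low replicate 3, and 0 fell without KRAS_CL replicate 1 or any 1 of the KRAS IKKa low arrays. Without KRAS_CL replicate 3, 1 dendritic cell gene rose and 4 fell, and 2 endothelial genes rose and 1 fell. The dendritic list also had 1 that rose without KRAS_CL replicate 2, and the erythroid and platelet list had 2 without KRAS IKKa low replicate 2. None of 15 markers of mast cells, basophils and eosinophils passed, by either adjustment (0.662), though 1 fell without KRAS_CL replicate 3.

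The remaining lists were not called by camera in the main test. NF-kB response genes rose in 6 and fell in 4 of 23 cases (6 and 6 adjusted over the list alone; camera adjusted p = 0.839), with Ccrl2 up by 3.36 ± 0.20 and the receptor gene Tlr2 down to 12.15 ± 0.58 from 14.85 ± 0.14. Matrix remodelling genes rose in 7 and fell in 6 of 24 cases (8 and 8 adjusted over the list alone; 0.662). The protease gene Plau rose by 1.43 ± 0.17, and the inhibitor gene Timp1 fell by 5.41 ± 0.67 (KRAS_CL arrays at 13.52, 13.94 and 11.02). Matrix genes that fell numbered 10 without KRAS_CL replicate 3 and 3 without replicate 2 of either group, and leaving out any array but KRAS_CL replicate 3 left 3 or 4 that rose. Immune regulation genes rose in 5 and fell in 6 of 22 cases (5 and 7 adjusted over the list alone; 0.567). Cd274, which encodes PD-L1, fell by 1.23 ± 0.16, Pdcd1lg2 fell by 3.15 ± 0.46 and Cd47 fell by 1.54 ± 0.15. Counts that rose and fell were 3 and 0 of 11 for NADPH oxidase (3 and 1 adjusted over the list alone; 0.479), 4 and 5 of 21 for stress response (4 and 6; 0.343), 2 and 0 of 11 for heat shock (2 and 0; 0.562), 2 and 1 of 20 for complement and Fc receptors (2 and 1; 0.449) and 1 and 4 of 17 for inflammasome and pyroptosis (2 and 5; 0.0606). The inflammasome list was called lower with quantile normalization (adjusted p = 0.0495) and without KRAS_CL replicate 1 (0.0409), and 2 of its genes rose without KRAS_CL replicate 3 or KRAS IKKa low replicate 2. In the heat shock list 2 and in the complement list 3 fell without KRAS_CL replicate 3. Of the heat shock genes 1 rose without KRAS_CL replicate 2 or KRAS IKKa low replicate 1 or 3, and 0 complement genes fell without KRAS_CL replicate 2. Without KRAS_CL replicate 1, 1 NADPH oxidase gene fell. NF-kB genes that fell numbered 2 without KRAS IKKa low replicate 1. Stress response genes that fell numbered 8 without KRAS_CL replicate 3, 2 without KRAS IKKa low replicate 1 and 3 without replicate 2 of either group. Immediate early genes, which respond to handling, rose in 1 and fell in 5 of 21 cases, also adjusted over the list alone, with a median of 0.01. Without KRAS_CL replicate 2, 2 of them fell, and without KRAS IKKa low replicate 2 or 3, 3 fell.

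**Figure D3:**
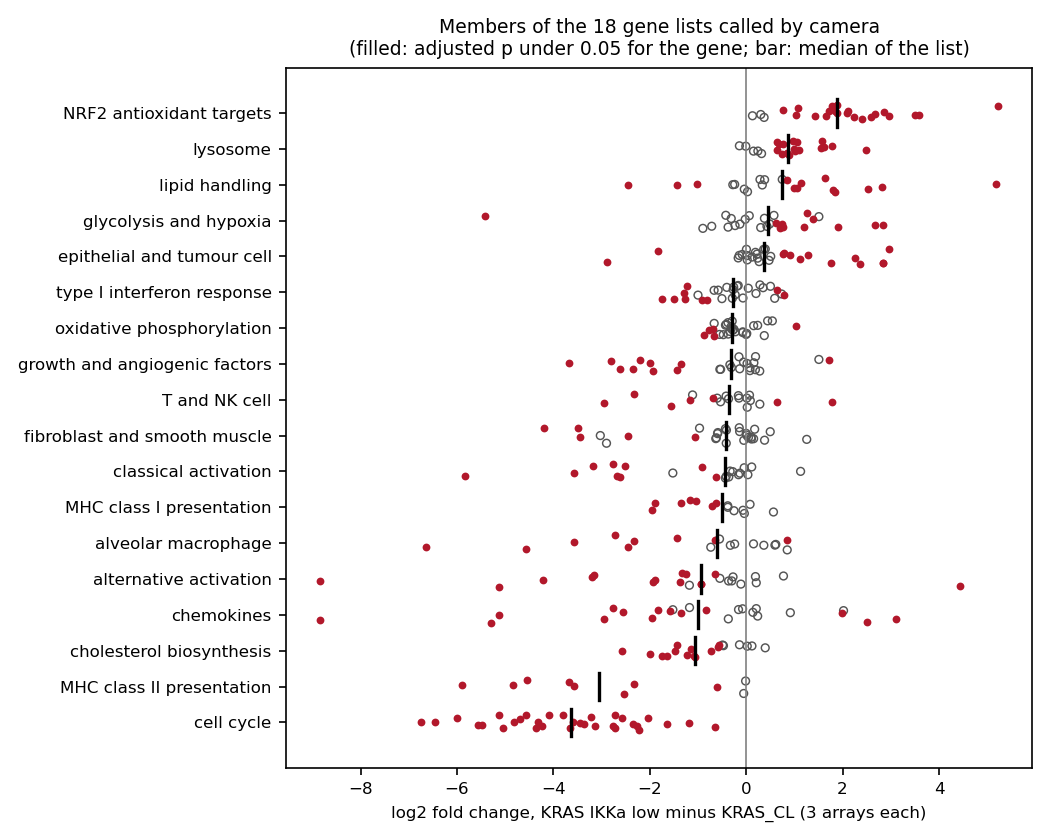
Log2 fold change, KRAS IKKa low minus KRAS_CL (3 arrays each), of every measured member of the 18 lists called by camera, filled where the gene's adjusted p was under 0.05, with a bar at each list's median. The medians run from -3.62 for the cell cycle list to 1.89 for the NRF2 list, and 13 of the 18 lists shifted downward.

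Camera with the preset correlation called 18 of 35 lists, 5 higher and 13 lower. Some lists share members, so their calls are not independent. Ccl17 is in the alternative activation and chemokine lists, and Il18 in the classical activation and alveolar macrophage lists. None of these calls held with a correlation estimated for each list. The growth and angiogenic factor list had an estimated correlation of 0.0097, close to the preset 0.01. Its unadjusted camera p still went from 0.00471 to 0.0472, so correlation between genes alone does not account for that loss. Fry, which asks whether a list's genes move 1 way on balance, called 22. It shared 14 calls with camera. The interferon, oxidative phosphorylation, T and NK cell and fibroblast lists were not called by fry (adjusted p = 0.150, 0.131, 0.0771 and 0.132), while 8 lists not called by camera were.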

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

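All tests of explanations in this part were chosen after the result was seen, apart from the counts over other splits of the arrays, which were planned but whose outcomes were seen before their predictions were written. Among the 2634 transcript cluster probe sets without a gene name, which entered no comparison above, 186 were higher and 150 lower on KRAS IKKa low arrays, a signal in data outside the main measurement. The one that rose farthest went from 4.98 ± 0.15 on KRAS_CL arrays, a mean below the background line, to 11.16 ± 0.11 on KRAS IKKa low arrays (SD, n = 3). Its probe set name carries the same Y chromosome prefix as those of Eif2s3y and Uty. It is therefore not a signal separate from the Y-linked difference described next. The one that fell farthest moved by -4.95 on the log2 scale.

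The Y-linked genes Eif2s3y and Uty lay well above the background line on all 3 KRAS IKKa low arrays and below it on every KRAS_CL array. Kdm5d was also higher on the KRAS IKKa low arrays. A single array under the wrong label would correlate more closely with the other group across the remaining genes, and 0 arrays did. Such correlations cannot show an exchange of the labels of whole groups. Male cells other than macrophages, if numerous enough to lower the X-linked genes, would have lowered the pan-macrophage genes as much. The pan-macrophage genes had a median of -0.012 and a lower quartile of -0.25, and 5 of the 15 rose while none fell. The X-linked partner genes had a median of -0.89. These values argue against such carry-over, for the share of male cells that the X-linked fall would need. A smaller share of male cells, too few to lower the X-linked genes, was not tested. Male mice in 1 group and female mice in the other would raise the Y-linked genes and lower their X-linked partners, and the values went that way. The 4 X-linked partner genes had a median log2 fold change of -0.89. Singly they moved by -1.18 ± 0.16 (Eif2s3x), -1.01 ± 0.16 (Kdm6a), -0.78 ± 0.20 (Kdm5c) and -0.47 ± 0.16 (Ddx3x), log2 ± SE. Of these, Ddx3x did not pass. The labels give no sex to check this against. The biological difference named by the design, the injected cells, then cannot be separated from sex in any result of this comparison, and this was not tested further.

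Cell cycle genes were lower on KRAS IKKa low arrays. Dividing epithelial tumour cells in the KRAS_CL samples would bring epithelial transcripts. However, only 2 of the 28 markers were lower on KRAS IKKa low arrays against 11 that were higher. Krt8 and Krt18 averaged 6.17 and 7.33 on KRAS_CL arrays. Tumour cells without epithelial transcripts were not tested. Dividing fibroblasts or smooth muscle cells stay open: on KRAS_CL replicate 3, with Acta2 and Tagln at the KRAS IKKa low level, the cell cycle list still lay 2.95 above the KRAS IKKa low mean, but this is 1 array and Dcn remained 3.58 above that mean on it. A difference in macrophage division between the groups stays open too, and was not tested.

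NRF2 targets were higher on KRAS IKKa low arrays. Scaling of the arrays does not account for it, since the median of the list was 1.83 after quantile normalization. Epithelial tumour cells carried over into the KRAS IKKa low samples stay open. The epithelial and tumour markers had a median log2 fold change of 0.38, below that of the NRF2 list. But most of them lay near background, and a small share of cells with high NRF2 activity would not be excluded. A response of the macrophages themselves may equally contribute and was not tested.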

How the results depend on the processing

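The alternative without KRAS_CL replicates 1 and 2 was chosen after seeing the data, and the others were planned. It leaves 1 KRAS_CL array against 3, the one picked for its low smooth muscle markers, and the spread then comes from the KRAS IKKa low arrays alone. Only its moved and reversed values are given here, and they decide no call. The count of 3207 genes stayed within 1.5 times under all but 2 of them: 1702 genes (760 higher, 942 lower) with a log2 change of at least 1, a subset by construction, and 1313 (669 and 644) without moderation. Leaving out each array gave 2202 to 4040 genes, 1067 to 1953 higher and 1070 to 2087 lower, and 16 to 19 lists. The 1067 came without KRAS IKKa low replicate 1, and with KRAS_CL replicates 1 and 2 left out 1073 genes were higher. Camera with an estimated correlation called 0 of 35 lists where the preset called 18 and fry 22. Fry shared 14 of the 18, lost 4 and added 8. The cause of the other shifts was not tested. The median over all genes moved from 0.01 to 0.02 and 0.03 with quantile normalization and median centring.

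Some uncalled lists turned direction. The NF-kB list had a median of -0.12 without the dimmest 50% of genes and 0.015 with KRAS_CL replicates 1 and 2 left out, where the endothelial list had -0.11. Leaving out each array gave medians of -0.14 to 0.0075 for NF-kB, -0.10 to 0.020 for endothelium, -0.087 to 0.046 for heat shock, 0.095 to 0.48 for complement and Fc receptors, -0.32 to 0.12 for monocytes and -0.60 to 0.038 for matrix remodelling. The test's direction, not the median alone, decided these, and the cause was not tested. Over the called lists, with camera at the preset correlation throughout, 252 results under the alternatives kept their direction and call and 17 lost the call, 4 of these with 1 KRAS_CL array left. Over the called genes that the text names, the counts were 1527 and 30, and none of them turned direction. These gene counts include results with 1 KRAS_CL array left. The uncalled genes Ddx3x, Acta2 and Tagln gained a call in 8 results, 3 with array weights, 3 without KRAS_CL replicate 3, 1 with trend and robust estimation (Ddx3x) and 1 with the block (Tagln). By the same camera test uncalled lists gained a call in 9 results, of which 4 had 1 KRAS_CL array left. The others were the inflammasome list with quantile normalization (0.0495) and without KRAS_CL replicate 1 (0.0409), the B and plasma cell list with the block (0.0344) and without KRAS IKKa low replicate 2 (0.0186), and the interstitial macrophage list without that array (0.0155).

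A replicate block by the shared numbers gave 2952 genes and 19 lists. The labels do not state that the numbers pair the arrays. The deviations of same-numbered arrays correlated at 0.10, -0.09 and -0.01 across genes, and not every array correlated best with its own number. Within KRAS_CL the deviations of replicate 3 correlated at -0.75 and -0.69 with those of replicates 1 and 2. Deviations from the mean of the same 3 arrays are negatively correlated by construction. Within KRAS IKKa low they correlated at -0.56, -0.40 and -0.53. A small effect shared by number could be hidden by the distance of replicate 3 and is not excluded. In splits of the 6 arrays into 3 and 3, 1 of 10 gave as many genes and 1 of 10 as many lists, in each case the real split, and the highest of the others gave 0 genes and 13 lists. With 10 splits a share under 0.05 cannot be reached. Signal over background limits the 9772 genes below the line on all 6 arrays.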

Other observations

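All tests in this part used gene families chosen after seeing the data. Replication-dependent histone genes fell together: 43 of 49 measured members were lower on KRAS IKKa low arrays and none rose (44 and 0 adjusted over the list alone), with a median log2 fold change of -3.09. The camera p was 1.75e-33 at the preset correlation and p = 0.0541 with an estimated correlation. These genes are near copies of each other, so single members are uncertain.

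Glutathione S-transferase genes rose in 12 and fell in 2 of 21 cases (13 and 2 adjusted over the list alone), with a median of 0.999 (camera p = 9.87e-08, and p = 0.00445 with an estimated correlation). Beside Gsta3, Gsta4 went from 6.27 ± 0.22 to 10.56 ± 0.16, its KRAS_CL mean below the background line, and Gstm2 from 8.64 ± 0.05 to 11.93 ± 0.24 (SD, n = 3). Ribosomal protein genes rose in 1 and fell in 4 of 57 cases (1 and 0 adjusted over the list alone), with a median of -0.21 (camera p = 0.00596, and p = 0.519 with an estimated correlation).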
